A study of Mus musculus with 12 samples.

How the data were processed

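Livers of 6 WT and 6 Hsd17b13 KO mice on CDAA-HFD were measured by RNA sequencing, 1 library per mouse. Per the labels' protocols, RNA was taken from 25 to 100 mg of liver with TRIzol and RNeasy columns including DNase treatment, and libraries were made from 1 µg of total RNA with NEBNext globin and rRNA depletion and a directional kit. The molecule label says polyA RNA, which differs from the depletion named in the protocol, and nothing used here settles it. The submitters' processing notes name the mm10 genome, Partek 10.0, STAR 2.7.3a and DESeq2 1.14.1 without a role for each. The counting tool, its annotation and its strand setting are not given in the sources used here.

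The authors deposited 1 table of 20143 genes by 12 libraries whose values are CPM: each column sums to 1000000 over the listed genes. Of the low values, 68.7% to 70.9% per library lay within 0.02 steps of a whole multiple of 1 common step, where evenly spread values would give 4%, which argues against scaling by gene length. The rest were fractional, so whole reads were not recovered and no count test was run. The step gave the depth of each library, and counting errors derived from it cover counting only, since reads without molecular identifiers are not independent molecules. The lowest gene mean in the table was 0.151 CPM. Of the IDs, 20055 had a symbol and a position in GENCODE annotation of mm10 and 88 did not; the latter hold 9.59% of the counts. For 16 symbols shared by more than 1 ID each ID was kept apart. All 12 columns were mapped to samples by their titles, and group and mouse number come from the labels. Pairs of WT or KO libraries differed well beyond counting noise (median chi-square per gene 5.20 to 20.5, against 0.455 for noise alone), so each counts as its own sample.

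Before the data were examined, the design, the gene lists, the rule for named genes and most alternatives were fixed. The design assumed normalized counts; the CPM found call for the same test on a log scale, which was used unchanged. CPM values were converted to log2(CPM + 1), genes with a mean of at least 10 CPM over the 12 libraries were kept (9186), and KO was compared with WT by limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). No covariate was used, as the labels give no batch, litter or sex.

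From 50 gene lists covering interferon responses, fibrosis, liver cell types, metabolism, RNA handling and neighbouring tissue, the 39 with at least 5 tested members were tested with camera of limma (preset inter-gene correlation of 0.01, two-sided, adjusted over 39 lists). Camera with an estimated correlation and fry were run beside it. Each list also received a score per mouse, the mean log2(CPM + 1) of its tested members, compared by an exact two-sided permutation test over all 924 assignments and adjusted over the same 39 lists. A further 6 lists reached 5 members only at a mean of at least 1 CPM, and 5 were described by their values. Counts of list members that rose or fell are given over all genes and adjusted over the list alone. The type I interferon and the type II interferon lists share 0 tested genes, as do the fibrosis and activated stellate lists.

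The rule for named genes took Hsd17b13, the 12 called genes with the largest rise and the 12 with the largest fall that had a mean of at least 50 CPM in the higher group and a proper symbol. Where fewer than 5 passed in a direction, it took the 5 with the smallest p as values without a call. It also took up to 4 members with the smallest p from each list described, and Col1a1, Acta2, Timp1, Isg15, Irf7, Cxcl10, Dpyd, Spp1, Hsd17b11 and Nnt. Of the genes so taken, 2 are not reported here. Under this rule Pebp1, Rplp0 and Scarb2 are named. The other called genes, which have lower means or predicted-gene names, were named after their values were seen. So were Cela1, Gzmb, Gzma and Klrk1. Copies of called genes were sought among GENCODE transcripts with BLASTN 2.17.0 (at least 95% identity over at least 500 bases), and positions are 1-based on mm10. Enrichment on chromosome 5 was tested with Fisher's exact test in SciPy 1.17.1 (Python 3.11.15).

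The limma, camera and score steps were tested on simulated data of 6 against 6 libraries with 9186 genes. Of 50 genes changed by each fold, 84% were recovered at 1.5-fold, 90% at 2-fold, 98% at 3-fold and 100% at 4-fold, with 19 false calls among 205. A simulation with nothing changed gave 0 calls, and camera called the 1 list that had been shifted and no other of the 39. Genes were drawn independently of each other in these simulations. They therefore do not test how often camera calls unshifted lists whose members are correlated.

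The alternatives tried were pseudocounts of 0.5 and 10, quantile normalization, rescaling to a common total, no filter and means of at least 100 CPM. Others were fits without the mean trend, with library weights or with a minimum 1.5-fold change, the mouse number as a block, and leaving out each library in turn. Alternatives added after seeing the data were a mean of at least 1 CPM, a term for mice 1 to 3 against mice 4 to 6, CPM without the 2 most abundant features that have no symbol, median-of-ratios scaling, leaving out chromosome 5 genes and copies, and leaving out KO mice 1 and 3 or WT mouse 1 and KO mouse 3. Tests on reads, planned for the case that whole reads could be recovered, were not run.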

Results

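Liver RNA was sequenced from 12 mice, 6 wild-type (WT) and 6 lacking Hsd17b13 (KO), with 1 library per mouse and mice numbered 1 to 6 in each group. All mice ate a choline-deficient, amino acid-defined high-fat diet (CDAA-HFD) for 12 weeks from an age of 8 to 10 weeks. This diet produces a fatty, inflamed and scarred liver. Hsd17b13 encodes an enzyme of the hepatocyte lipid droplet. The deposited table gave 20143 genes in CPM, counts scaled to a sum of 1000000 per library. By the smallest step between its values, 1 CPM stood for 46.3 to 77.9 counts depending on the library, 62.4 ± 9.08 in WT and 59.0 ± 11.1 in KO. At these depths 10 CPM, the lowest mean tested, stood for 463 to 779 counts, with a counting error of at most 4.65%. The series concerns interferon signalling and fibrosis in steatohepatitis without Hsd17b13. Its single comparison, KO against WT, asks which transcripts differ when the gene is missing. Values are mean ± SD CPM of 6 mice per group, and log2 differences are KO minus WT of log2(CPM + 1), which understates the change of low genes. The labels give 6 mice per group and no litter, so p-values of limma and of the permutation tests measure the spread between these mice. Camera with its preset correlation compares the genes of a list with the other genes. Its p-values therefore do not measure that spread.

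Hsd17b13 (ENSMUSG00000034528, chromosome 5, 103955440 to 103977410, mm10, protein coding) was nearly lost in KO, at 1.18 ± 0.181 CPM against 347 ± 36 in WT. WT mice 1 to 6 held 318, 393, 315, 362, 315 and 382 CPM. KO mice 1 to 6 held 1.40, 1.23, 0.992, 1.34, 0.956 and 1.1 CPM, which came from 53 to 94 counts each. The WT mean was 295-fold above the KO mean (log2 difference -7.32, SE 0.08, limma adjusted p = 1.31e-16). The exact permutation p of 0.00216 is the smallest that the 924 assignments of 12 mice to 2 groups of 6 can give. Every library followed its genotype label. Where in the gene the deletion lies is not given in the sources used here. Hsd17b11, a related lipid droplet enzyme encoded nearby, was at 134 ± 13.7 CPM in WT and 134 ± 9.92 in KO (log2 difference 0.00, SE 0.07, adjusted p = 0.995).

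Beyond the targeted gene, few transcripts passed the test in KO liver. Pebp1, a phospholipid-binding inhibitor of Raf kinase signalling, rose from 99.6 ± 6.94 to 265 ± 47.6 CPM (log2 difference 1.38, SE 0.11, adjusted p = 1.29e-05). Cxcl9, a T cell chemokine induced by interferon-gamma, rose from 12.6 ± 2.51 to 25.6 ± 5.78 CPM (log2 difference 0.95, SE 0.15, adjusted p = 0.0133). Gpat3, an acyltransferase of triglyceride synthesis, rose from 26.6 ± 4.47 to 42.3 ± 3.80 CPM (log2 difference 0.66, adjusted p = 0.0133), and Coq5, a methyltransferase of coenzyme Q synthesis, rose from 16.6 ± 1.13 to 24.5 ± 2.49 (0.53, adjusted p = 0.0045). Scarb2, a lysosomal membrane protein, fell from 195 ± 7.90 to 146 ± 2.74 CPM (log2 difference -0.42, SE 0.04, adjusted p = 0.000178). Ltbp2, a matrix protein that associates with elastic microfibrils, fell from 30.4 ± 11.3 to 13.5 ± 2.22 CPM (log2 difference -1.06, SE 0.18, adjusted p = 0.0356).

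Of 9186 genes tested with limma, 14 passed an adjusted p of 0.05, 10 higher and 4 lower in KO. At an unadjusted p under 0.05 there were 900 genes (414 higher, 486 lower), where chance alone gives 459. The remaining calls were Rplp0, Eif4e3 (18.3 ± 1.58 to 24 ± 1.70 CPM, log2 difference 0.37, adjusted p = 0.0489), Gbp11 and the pseudogenes Gm8730, Gm9625, Gm10819 and Gm9824; Gbp11 is annotated as a polymorphic pseudogene. The rule for named genes gave 6 more genes that did not pass. Rmdn3 (45.3 to 53.9 CPM, adjusted p = 0.103), Afm (100.1 to 130.3, 0.116), Zcchc2 (54.5 to 64.7, 0.124) and Gbp7 (35.5 to 59.1, 0.124) had higher KO means, and Pdgfrb (54.5 to 39.8, 0.0854) and Igfbp7 (151 to 116, 0.0984) had lower ones. The count of calls moved to 9 without WT mouse 3, where Cxcl9 and Gpat3 no longer passed, and to 25 without KO mouse 3. Rplp0, Ltbp2 and Eif4e3 passed in only 2, 4 and 2 of the 12 fits that left out 1 mouse each, while Scarb2, Pebp1, Coq5, Gbp11 and the 4 pseudogenes passed in all 12.

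The called genes clustered on chromosome 5, which carries Hsd17b13. Apart from Hsd17b13, 7 of 13 called genes with a position lay there (Cxcl9, Scarb2, Gpat3, Gbp11, Coq5, Rplp0 and Pebp1), against 6.48% of the 9160 tested genes (odds ratio 17, Fisher's exact p = 5.66e-06). They lay 1.37 to 13.3 Mb from Hsd17b13, between 92.3 and 117 Mb, and 0 of the 7 tested genes within 1 Mb passed, although 3 had an unadjusted p under 0.05. Within 30 Mb of Hsd17b13, 29 of 265 tested genes (10.9%) had an unadjusted p under 0.01, compared with 9 of 329 (2.74%) on the rest of the chromosome and 3.29% on others. Cxcl9 starts at 92321347, Scarb2 spans 92441314 to 92506833, Rplp0 spans 115559467 to 115563727 and Pebp1 spans 117282654 to 117287625 on this chromosome (mm10). With chromosome 5 genes and their copies left out, limma called 0 of 8587 genes, and 812 had an unadjusted p under 0.05.

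**Figure D1:**
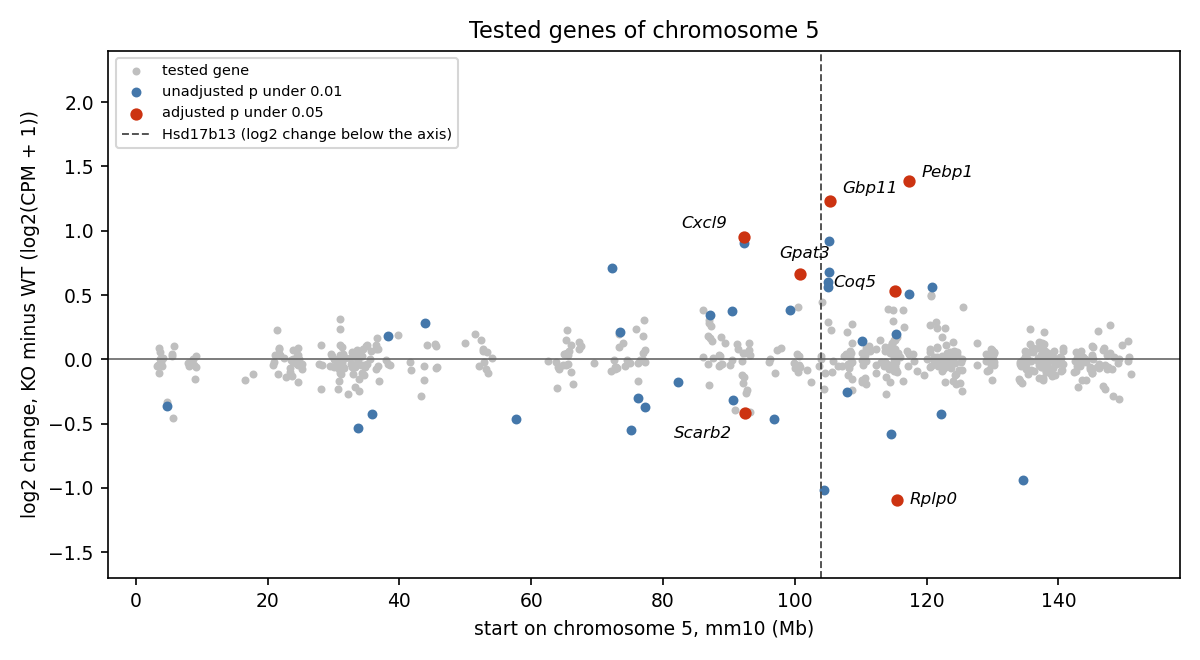
Log2 difference, KO minus WT, of each tested gene on chromosome 5 against its start in Mb (mm10), with genes of unadjusted p under 0.01 and of adjusted p under 0.05 coloured. The 7 called genes other than Hsd17b13 lie between 92.3 and 117 Mb, on both sides of Hsd17b13, whose position is the dashed line and whose value of -7.32 lies below the axis.

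Some of these genes have near-identical copies elsewhere, which makes their calls uncertain. Rplp0, a protein of the large ribosomal subunit, fell from 350.0 ± 14 to 172 ± 65.5 CPM (log2 difference -1.10, SE 0.18, adjusted p = 0.0285). Its processed pseudogene Gm8730 (98.7% identical, chromosome 8) rose from 28.8 ± 1.85 to 171 ± 41.7 CPM (adjusted p = 5.32e-07). Another, Gm9625 (97.4% identical, chromosome 13), rose from 29.0 ± 1.16 to 67.7 ± 8.93 CPM (adjusted p = 2.12e-06). Rplp0 and its 4 measured copies summed to 416 ± 15.9 CPM in WT and 422 ± 19.1 in KO. Gm8730 took 6.49% to 7.43% of that sum in WT, 47.3% to 48.5% in KO mice 2, 4, 5 and 6, and 26.8% and 26.9% in KO mice 1 and 3. The midpoint between the medians of WT and of KO mice 2, 4, 5 and 6 was 27.3%. Pebp1 has the copies Gm10819 (99.1% identical, 14.2 ± 0.692 to 41.1 ± 6.93 CPM, adjusted p = 2.12e-06) and Gm9824 (98.9% identical, 15.1 ± 1.48 to 44.7 ± 10.1, adjusted p = 6.01e-05). The sum of Pebp1 and these copies went from 129 ± 8.60 to 351 ± 64.4 CPM. Pebp1 itself was at 195 and 214 CPM in KO mice 1 and 3 against 288 to 308 in the other KO mice. Gbp11, which went from 10.1 ± 2.13 to 25.8 ± 8.31 CPM (adjusted p = 0.0133), is 95.9% identical to Gbp8 over 702 bases. An antisense gene overlaps Ltbp2, and no source used here says whether counting used the strand.

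Interferon-stimulated genes were higher as groups in KO liver. Of 35 tested genes of the type II interferon and MHC class I list (GTPases, chemokines and antigen presentation), all 35 had positive differences, with a median of 0.36 (camera adjusted p = 1.09e-34; adjusted p = 0.253 with an estimated correlation). Over all genes tested 1 of them rose, Cxcl9. It is 1 of the 5 members on chromosome 5, and the members elsewhere had a median of 0.346. Of the 35, 30 rose when adjusted over the list alone, 0 fell and 5 did not pass. Examples with no call over all genes are the immunoproteasome subunits Psmb9 (17.8 ± 1.87 to 24.6 ± 3.24 CPM, adjusted p = 0.0854) and Psmb8 (32.5 ± 3.20 to 42.5 ± 5.17, 0.124). Others are the GTPase Gbp9 (22.8 ± 2.03 to 35.7 ± 8.19, 0.0964) and the chemokine Cxcl10 (12.7 ± 3.98 to 25.1 ± 8.51, 0.153). The list score, the mean log2 value of its members per mouse, was 0.46 ± 0.11 (SE) higher in KO (exact permutation p = 0.00649, adjusted p = 0.0506), and 5 of 6 KO mice lay above every WT mouse.

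The type I interferon list moved the same way with a wider spread between mice. Of 43 tested genes 42 had positive differences, with a median of 0.51 (camera adjusted p = 2.46e-25; adjusted p = 0.26 with an estimated correlation). On chromosome 5 lie 6 of the 43, and the members elsewhere had a median of 0.529. Over all genes tested 0 rose and 0 fell with limma, and 31 had an unadjusted p under 0.05. There were 28 that rose when adjusted over the list alone, 0 that fell and 15 that did not pass. The nucleic acid sensor Zbp1 went from 20.9 ± 4.62 to 40.7 ± 14.8 CPM (adjusted p = 0.17), and Gbp4 from 8.67 ± 1.96 to 13.4 ± 3.03 (0.172). The ubiquitin ligase Dtx3l went from 108 ± 8.07 to 142 ± 24.8 (0.178) and the ligase Herc6 from 29.3 ± 4.71 to 47.3 ± 14.1 (0.198). The transcription factor Irf7 was at 85.3 ± 22.4 and 141 ± 52.6 CPM (adjusted p = 0.291), and the ubiquitin-like modifier Isg15 at 19.2 ± 8.16 and 40.2 ± 24.3 (0.343). The score was 0.56 ± 0.23 (SE) higher in KO (exact permutation p = 0.0368, adjusted p = 0.205), with 4 of 6 KO mice above every WT mouse. KO mice 1 and 3 scored 5.25 and 4.80, near the WT mean of 5.02, and the other KO mice 5.66 to 6.26. The 17 tested interferon receptors and nucleic acid sensors were not called (median 0.03, camera adjusted p = 0.224). They had 0 members that rose or fell over all genes or adjusted over the list alone and 4 with an unadjusted p under 0.05. At a mean of at least 1 CPM camera called this list higher (20 genes, median 0.04, adjusted p = 0.0409; 0.449 with an estimated correlation), as it did without WT mouse 1 and KO mouse 3. Its score passed the exact permutation test with median-of-ratios scaling (adjusted p = 0.0241, against 0.394 as reported).

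Antigen presentation by MHC class II leaned upwards. All 7 tested genes had positive differences with a median of 0.32 (camera adjusted p = 1.96e-05; adjusted p = 0.297 with an estimated correlation). With limma 0 rose over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. H2-Eb1 was at 66.0 ± 17.5 CPM in WT and 85.5 ± 12.2 in KO (adjusted p = 0.342), and Cd74, the invariant chain, at 242 ± 56.4 and 306 ± 49.9 (0.412). H2-Ab1 was at 79.4 ± 19.6 and 99.4 ± 15.3 (0.441), and the class II transactivator Ciita at 13.9 ± 3.38 and 17.4 ± 2.59 (0.497). The score was 0.31 ± 0.15 (SE) higher in KO (exact permutation p = 0.0606, adjusted p = 0.246), with 2 of 6 KO mice above every WT mouse.

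Collagen and matrix genes were lower as a group in KO liver. Of 32 tested fibrosis and matrix genes 29 had negative differences, with a median of -0.36 (camera adjusted p = 6.47e-17; adjusted p = 0.253 with an estimated correlation). Over all genes tested 0 rose and 0 fell with limma and 22 had an unadjusted p under 0.05. The test adjusted over the list alone gave 21 that fell, 0 that rose and 11 that did not pass. Dermatopontin (Dpt) was at 26.2 ± 9.18 CPM in WT and 13.6 ± 1.1 in KO (log2 difference -0.85, adjusted p = 0.0515), and the metalloproteinase inhibitor Timp2 at 75.3 ± 17.2 and 49.0 ± 6.48 (0.114). Elastin (Eln) was at 18.7 ± 7.34 and 9.04 ± 2.29 (0.116) and the gelatinase Mmp2 at 26.6 ± 7.87 and 15.4 ± 2.98 (0.119). The fibrillar collagen gene Col1a1 was at 285 ± 70.8 and 199 ± 27.1 (log2 difference -0.49, adjusted p = 0.217). Timp1 (5.10 ± 0.906 and 3.62 ± 0.360 CPM) and Acta2 (5.57 ± 1.30 and 4.32 ± 0.464) lay under the minimum of 10 CPM and did not pass in a fit of all genes (adjusted p = 0.111 and 0.397). The list score differed by -0.37 (SE 0.11, exact permutation p = 0.00649, adjusted p = 0.0506), with 5 of 6 KO mice below every WT mouse.

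Markers of activated stellate cells, the collagen-producing cells of the injured liver, had negative differences in all 10 tested genes (median -0.32, camera adjusted p = 7.99e-07; adjusted p = 0.253 with an estimated correlation). With limma 0 fell over all genes and 7 had an unadjusted p under 0.05. Of the 10, 7 fell when adjusted over the list alone, 0 rose and 3 did not pass. The growth factor receptors Pdgfrb (54.5 ± 7.74 to 39.8 ± 3.66 CPM, adjusted p = 0.0854) and Pdgfra (53.5 ± 16.7 to 35.1 ± 3.91, 0.17) had lower KO means with no call. So did the transcription factor Sox4 (28.7 ± 10.3 to 15.8 ± 3.93, 0.139) and the matricellular Ccn2 (23.1 ± 5.64 to 13.3 ± 6.25, 0.187). The score difference was -0.37 (SE 0.10, exact permutation p = 0.00433, adjusted p = 0.0506), with 5 of 6 KO mice below every WT mouse. Markers of quiescent stellate cells leaned the other way, with 7 of 10 tested genes positive and a median of 0.10 (camera adjusted p = 0.00412; adjusted p = 0.253 with an estimated correlation). Adjusted over the list alone 3 rose and 0 fell, and over all genes 0 passed with limma, 3 at an unadjusted p under 0.05. Those 3 were the collectin Colec10 (16.8 ± 4.12 to 27.1 ± 4.74 CPM, adjusted p = 0.154), the retinol esterifying enzyme Lrat (38.3 ± 6.34 to 52.2 ± 7.0, 0.158) and Ecm1 (62.0 ± 8.64 to 80.2 ± 14.3, 0.275). Next by p came Colec11 (32.8 ± 2.94 to 36.9 ± 5.56, 0.657), which did not reach an unadjusted p under 0.05. The score of the quiescent list was 0.17 ± 0.06 (SE) higher (exact permutation p = 0.0173, adjusted p = 0.113, 5 of 6 KO mice above every WT mouse).

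Resident Kupffer cell markers and markers of recruited macrophages moved in opposite directions. All 7 tested Kupffer genes had positive differences (median 0.37, camera adjusted p = 1.13e-07; adjusted p = 0.253 with an estimated correlation). Of the 7, 6 rose when adjusted over the list alone, 0 fell and 1 did not pass. Over all genes 0 passed with limma, 6 at an unadjusted p under 0.05. They include Cd5l (168 ± 29.1 to 237 ± 26.5 CPM, adjusted p = 0.134), the lectins Clec1b (15.1 ± 1.97 to 19.8 ± 2.25, 0.153) and Clec4f (81.9 ± 21.8 to 123 ± 29.0, 0.279) and the iron exporter Slc40a1 (192 ± 20.2 to 236 ± 20.4, 0.158). Their score was 0.37 ± 0.11 (SE) higher in KO (exact permutation p = 0.00649, adjusted p = 0.0506, 5 of 6 KO mice above every WT mouse). Of 24 tested genes of monocyte-derived and lipid-associated macrophages 21 had negative differences (median -0.30, camera adjusted p = 1.26e-07; adjusted p = 0.36 with an estimated correlation). In the test adjusted over the list alone 10 fell, 0 rose and 14 did not pass, and over all genes 0 passed with limma, 13 at an unadjusted p under 0.05. Lysozyme (Lyz2) was at 810.3 ± 162 CPM in WT and 536 ± 81.5 in KO (adjusted p = 0.12), the integrin Itgam at 30.2 ± 5.96 and 21.3 ± 3.17 (0.17), Cd63 at 40.0 ± 7.98 and 28.9 ± 4.12 (0.201) and Gpnmb at 625 ± 137 and 446 ± 73.5 (0.225). The score difference was -0.25 (SE 0.12, exact permutation p = 0.0693, adjusted p = 0.246, 2 of 6 KO mice below every WT mouse).

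Cholangiocyte and ductular reaction markers were the list with the most negative median. Of 9 tested genes 7 were negative (median -0.64, camera adjusted p = 1.68e-05; adjusted p = 0.253 with an estimated correlation). Adjusted over the list alone 6 fell, 0 rose and 3 did not pass, and over all genes 0 passed with limma, 6 at an unadjusted p under 0.05. Osteopontin (Spp1) was at 384 ± 171 CPM in WT and 182 ± 58.6 in KO (log2 difference -1.02, adjusted p = 0.158). The transcription factor Sox9 was at 34.2 ± 9.55 and 20.3 ± 5.35 (0.158), and Cd24a at 21.1 ± 9.17 and 9.71 ± 3.70 (0.17). The score difference was -0.52 (SE 0.15, exact permutation p = 0.00433, adjusted p = 0.0506), with 5 of 6 KO mice below every WT mouse. WT mouse 1 held 679.5 CPM of Spp1 and 224 CPM of Cela1, a pancreatic elastase gene that the other 5 WT mice held at 5.42 to 7.25. Without this mouse the cholangiocyte score differed by -0.43 (exact permutation p = 0.013), the smallest difference and highest p among the fits that left out 1 mouse. The combined score of the fibrosis and activated stellate lists still differed without it, by -0.29 (SE 0.08, exact permutation p = 0.00866).

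**Figure D2:**
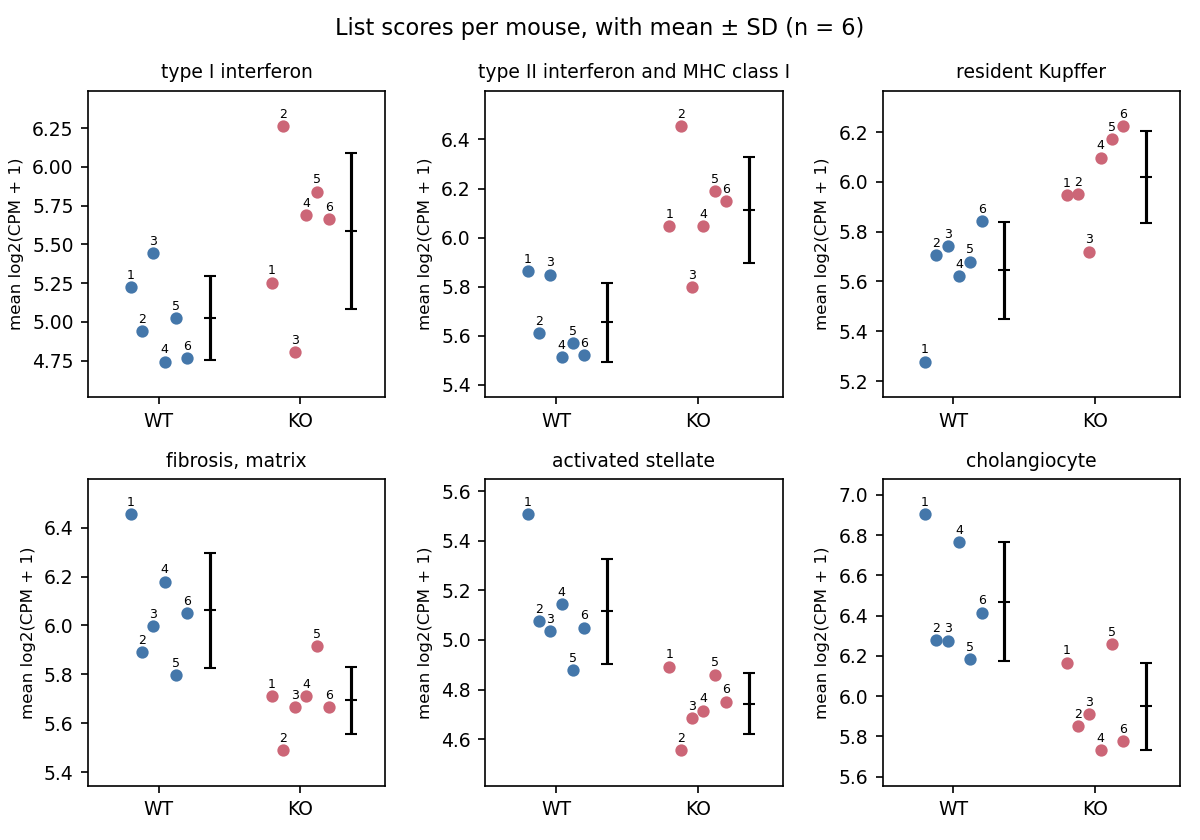
Mean log2(CPM + 1) of the members of 6 gene lists in each mouse, with mouse numbers beside the points and the mean ± SD (n = 6) of each group. For the type II interferon, Kupffer, fibrosis, activated stellate and cholangiocyte lists 5 of 6 KO mice lie beyond every WT mouse, and for the type I interferon list 4 do.

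Camera called small shifts of 15 further lists, 14 higher and 1 lower. They include hepatocyte markers (28 genes, median 0.11, adjusted p = 6.41e-05; 0.36 with an estimated correlation), and bile acid genes (26, 0.13, 0.000256; 0.26). Others are enzymes induced by xenobiotics through CAR and PXR (17, 0.21, 0.000197; 0.295), acute phase genes (22, 0.18, 0.000836; 0.428) and NRF2 targets (26, 0.11, 0.000998; 0.36). Sinusoidal endothelial markers were called as well (18 genes, median 0.15, adjusted p = 5.19e-05; 0.424 with an estimated correlation). Upward shifts were also called for retinoid (28 genes, median 0.05, adjusted p = 0.0166; 0.297 with an estimated correlation), male-biased (16, 0.21, 0.0166; 0.428), and cholesterol synthesis genes (25, 0.08, 0.0251; 0.618). The same holds for lipid droplet (23, 0.05, 0.0278; 0.253), lipogenesis (24, 0.04, 0.0291; 0.428), pericentral (22, 0.08, 0.0348; 0.428), pyrimidine (16, 0.05, 0.0429; 0.348) and circadian genes (17, 0.18, 0.0429; 0.428). Cell cycle genes were called lower (13, median -0.22, adjusted p = 0.0238; 0.428 with an estimated correlation). Of the 312 genes in these 15 lists 0 passed with limma over all genes tested, and 45 had an unadjusted p under 0.05. Adjusted over the list alone only the retinoid list had members that passed, 1 higher and 1 lower. Their scores differed by -0.20 to 0.20 with exact permutation p from 0.0433 to 0.545 and adjusted p from 0.211 to 0.715. In the 12 fits without 1 mouse, camera kept the endothelial, hepatocyte, bile acid, NRF2 and xenobiotic calls in all 12 and the acute phase call in 11 (adjusted p = 0.113 without KO mouse 6). It kept the retinoid and male-biased calls in 9, cholesterol synthesis and cell cycle in 8, and pericentral and lipogenesis in 7. Lipid droplet, circadian and pyrimidine genes were called in 6, 5 and 4 of these fits. Each of the 12 mice ended at least 1 of these calls when left out, with adjusted p up to 0.708 (cholesterol synthesis without WT mouse 4). Leaving out 1 mouse moved the score difference by over 1.5 times in 7 of the 15 lists. The acute phase difference went from 0.19 to 0.06 without KO mouse 6 and to 0.29 without WT mouse 6, and the male-biased one from 0.17 to 0.07 without WT mouse 6 and to 0.29 without WT mouse 5. The cholesterol synthesis difference of 0.08 became 0.01 without KO mouse 6, 0.02 without WT mouse 4 and 0.05 without KO mouse 2. It became 0.15, 0.14 and 0.13 without WT mouse 5, KO mouse 1 and KO mouse 3. The circadian difference went from 0.19 to 0.10 and 0.12 without WT mice 1 and 2, and the pyrimidine one from 0.09 to 0.06 without KO mouse 4. The NRF2 difference of 0.09 became 0.06 without WT mouse 6 or KO mouse 2 and 0.15 without KO mouse 6, and lipogenesis went from 0.12 to 0.17 without KO mouse 1. With quantile normalization camera called 13 of the 39 lists in place of 24. The 11 lost were the hepatocyte (median 0.04 there, adjusted p = 0.112), NRF2, retinoid, male-biased, cholesterol synthesis, lipid droplet, lipogenesis, pericentral, pyrimidine, circadian and cell cycle lists. Dpyd, which starts pyrimidine breakdown, was at 288 ± 20.8 and 310.1 ± 12.7 CPM (log2 difference 0.11, adjusted p = 0.571).

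Another 14 lists showed no call by camera, among them fatty acid oxidation (32 genes, median 0.00, mean -0.06, adjusted p = 0.418), glucose metabolism (29, median 0.06, mean -0.02, 0.142) and choline and one-carbon metabolism (24, median 0.05, mean -0.01, 0.224). Periportal genes (18, 0.07, 0.152), the other Hsd17b enzymes (7, 0.04, 0.224), inflammatory cytokines (14, -0.06, 0.152) and the unfolded protein response (25, -0.01, 0.814) were not called either. Female-biased genes (5, median -0.07, mean 0.03, adjusted p = 0.902), fetal and tumour genes (6, -0.04, 0.12), immediate early genes (16, -0.16, 0.0936) and adipocyte markers (5, 0.12, 0.142) were also not called. Neither were mitochondrially encoded genes (13, 0.05, 0.296), RNAs without a poly(A) tail (11, 0.01, 0.509) and a list planned as the neighbourhood of Hsd17b13, of whose 12 tested genes 7 lie on chromosome 5 (median 0.01, mean -0.0049, 0.763). The fry test for change in either direction did call this neighbourhood list (adjusted p = 0.0229). For fatty acid oxidation, glucose metabolism, one-carbon metabolism, female-biased genes and the planned neighbourhood list the median and the mean had opposite signs. For the unfolded protein response camera gave an upward direction against a negative median and mean. Under another scaling the median had the opposite sign for fatty acid oxidation, the unfolded protein response, fetal and tumour, poly(A)-free and planned neighbourhood genes. Of the 213 genes in these lists 0 passed with limma over all genes and 27 had an unadjusted p under 0.05. Adjusted over the list alone, 2 fetal and tumour genes and 1 cytokine gene fell, and 1 gene rose and 1 fell among both the periportal and the planned neighbourhood genes. Camera did call some of these lists in other settings, immediate early genes in 7 of 25, periportal genes in 5 of 26, fetal and tumour genes in 3 of 25 and glucose metabolism in 2 of 26. Fatty acid oxidation, one-carbon metabolism and the planned neighbourhood list were called in 1 each. At a mean of at least 1 CPM the fetal and tumour list was called lower (15 genes, median -0.40, camera adjusted p = 0.00071; adjusted p = 0.244 with an estimated correlation). There 6 of its genes fell when adjusted over the list alone, and its score did not pass (exact permutation p = 0.00866, adjusted p = 0.0779). Nnt, a gene that differs between mouse substrains, was at 43.3 ± 3.73 and 43.1 ± 2.71 CPM (log2 difference -0.01, adjusted p = 0.983).

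**Figure D3:**
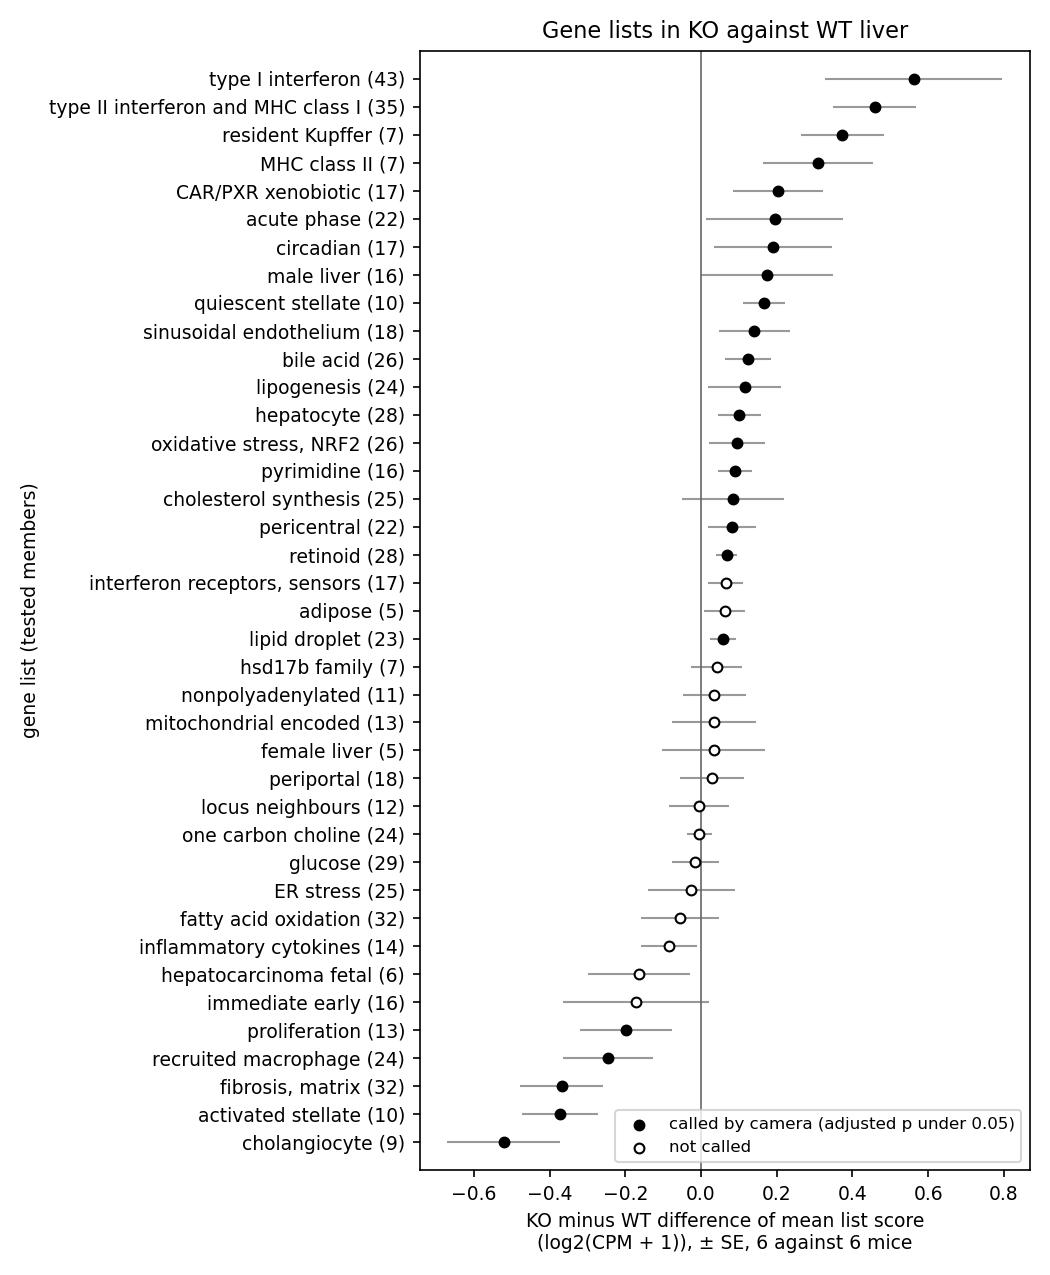
Difference of the mean list score, KO minus WT, in log2(CPM + 1) with its SE for the 39 tested gene lists, the number of tested members in brackets; filled points were called by camera. The scores run from -0.52 for cholangiocyte markers to 0.56 for type I interferon genes.

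Across the 39 lists camera with its preset correlation called 24, 19 higher and 5 lower. With a correlation estimated per list 0 of these calls held, and 7 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in one direction, called 1, type II interferon and MHC class I (adjusted p = 0.0466, all 35 genes positive). At a mean of at least 1 CPM that list no longer passed with fry (adjusted p = 0.051). The fry test for change in either direction called 5. They were type II interferon (adjusted p = 0.016), fibrosis, activated stellate, retinoid and the planned neighbourhood of Hsd17b13 (0.0229 each). With the mouse as the unit, 0 of 39 list scores passed the exact permutation test after adjustment and 8 had an unadjusted p under 0.05. The 5 lists with the adjusted p of 0.0506 were type II interferon, fibrosis, Kupffer, activated stellate and cholangiocyte.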

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

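All tests of explanations in this part, and the count of other splits of the mice, were chosen after the results were seen. Among the 208 sets of 6 mice examined, for named genes, list scores and depth in either group, 12 had a mouse far from the remaining 5, where chance gives 10.4, since chance marks about 1 in 20.

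WT mouse 1 stood alone above the other WT mice for Pdgfrb (69.2 CPM), Dpt (44.5), Mmp2 (41.7), Sox4 (48.5) and Pdgfra (86.2), and alone below them for Cd5l (112). WT mouse 3 stood alone for Isg15, at 34.6 CPM, and WT mouse 6 for the sinusoidal endothelial score, at 5.55. KO mouse 2 stood alone as the highest KO mouse for Isg15 (85.0 CPM) and Gbp7 (94.0) and the lowest for Cd63 (21.1). KO mouse 6 stood alone for the acute phase score, at 8.39.

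The real split of the mice gave 14 genes, and 4 of 100 splits, the real one included, gave as many or more. That met the limit set for this count by a margin of 1 split only, too narrow to exclude chance firmly. Without chromosome 5 genes and copies the real count was 0 with limma (812 genes at an unadjusted p under 0.05), so this says nothing of genes elsewhere. The highest other split gave 712 genes and set WT mice 1, 2 and 5 with KO mice 1, 2 and 3 against the rest, which points to a structure of the samples that the labels do not give. These 6 mice are also the 6 with positive values on the second principal component. For gene lists 6 of 100 splits gave at least the 24 camera calls, so chance cannot be excluded for that count. The other splits gave a median of 14 camera calls and at most 28.

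Called genes concentrated on chromosome 5. Summed over Rplp0 and its copies KO held 1.015 times the WT value, so reads moving between the copies could account for Rplp0, Gm8730 and Gm9625, while the Pebp1 sum was 2.719 times the WT value, which argues against that for Pebp1. Among genes that were not called and are in no interferon list, 17 of 248 within 30 Mb of Hsd17b13 had an unadjusted p under 0.01, against 251 of 8476 on other chromosomes (odds ratio 2.411, 95% interval 1.36 to 4.02, Fisher's exact p = 0.00201). KO mice 1 and 3, set apart by their Gm8730 share, held 0.403% and 0.285% of the WT level of Hsd17b13 (the others 0.275% to 0.386%), yet for Coq5 and Pebp1 they stood on average at 0.6215 of the way from WT to the other KO mice (these at 0.911 to 1.05), which argues against the missing Hsd17b13 alone for these genes. For Cxcl9, Scarb2, Gpat3 and Gbp11, KO mice 1 and 3 stood at 0.778 to 1.57 of the way from WT to the mean of all KO mice. On this other scale they stood at 0.563 and 0.706 for Coq5 and at 0.656 and 0.765 for Pebp1. The lowest value of the former genes, 0.778 for Cxcl9 in KO mouse 3, was thus close to that of Pebp1. A linked segment from another mouse strain is a candidate explanation, with its strain origin not tested, and an effect of the missing Hsd17b13 stays open for the other called genes of the chromosome.

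Interferon genes were higher in KO, by 0.52 ± 0.18 (SE) for both lists together (78 genes, exact permutation p = 0.0216). The 67 members off chromosome 5 differed by 0.5074 (SE 0.18), which argues against the chromosome 5 members as the cause, and without KO mouse 5, the omission that left the smallest ratio to its SE, the difference was 0.481 (SE 0.20), which argues against a single KO library. Leaving out KO mouse 2 gave the smallest difference, 0.41 (SE 0.16, exact permutation p = 0.0433). For the type I list alone that omission gave 0.43 (exact permutation p = 0.0714). More T cells may contribute, since the T cell score was 0.1767 higher (SE 0.10, exact permutation p = 0.117), too close to its spread to decide. KO mice 1 and 3 stood at 0.1727 of the way from WT to the other KO mice (at most 0.425, the others at least 0.761, SD 0.323). Single WT mice ran from -0.306 to 0.447 on this scale, and for the type II list KO mouse 1 stood among the others. The values lean against the missing Hsd17b13 alone, but 2 mice and this spread cannot decide. An effect of the genotype together with something else and one of the linked segment also stay open and were not tested.

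Fibrosis and activated stellate genes were lower in KO, by -0.37 (42 genes, SE 0.11, exact permutation p = 0.00433). A higher share of hepatocytes would lower all other cell markers alike, but the Kupffer and endothelial score minus the fibrosis score was 0.5751 higher in KO (SE 0.14, exact permutation p = 0.00216). These lists had already been seen to move apart, so that p overstates the support. The Kupffer and endothelial score alone was 0.21 higher (SE 0.09, exact permutation p = 0.0584). Cholangiocyte and recruited macrophage scores were lower in KO (-0.52 and -0.25), so a contribution of the hepatocyte share stays open. The quiescent stellate score was 0.1664 higher (SE 0.06, exact permutation p = 0.0173), which argues against fewer stellate cells of every state, though mainly through mice 4 to 6. It differed by 0.29 between these mice and by 0.04 between mice 1 to 3. KO mouse 3, at 5.39, lay below the WT mean of 5.41. Without WT mouse 4, the omission with the smallest ratio to its SE, the difference was -0.3498 (SE 0.12), and without WT mouse 1 it was -0.29 (SE 0.08), which argues against a single WT library as the cause. KO mice 1 and 3 stood at 0.9688 of the way from WT to the other KO mice, but these ran from 0.460 to 1.53 (WT SD 0.606), too wide to decide on the missing Hsd17b13 alone, and a change in stellate cell state with the genotype may remain as a hypothesis beside the linked segment.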

How the results depend on the processing

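The minimum of 1 CPM, median-of-ratios scaling, the fit without chromosome 5 and the fits leaving out pairs of mice were chosen after seeing the data. Hsd17b13 passed in every setting run, with log2 differences of -7.35 to -7.28 when 1 mouse was left out and -7.70 and -4.99 with pseudocounts of 0.5 and 10. Pebp1, Gm8730, Gm9625, Gm10819 and Gm9824 passed in every setting that included them, and Scarb2 and Coq5 in all but the minimum 1.5-fold change, which their differences of -0.42 and 0.53 miss by construction. Among the other values of 56 named genes under these settings, 1467 of 1566 kept direction and side of the threshold, 45 lost the call, 40 gained one, 14 with no call changed sign and 0 with a call did. Depth limits little at a mean of 10 CPM, and the spread between mice sets the precision.

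For genes, 14 calls (10 higher, 4 lower) became 29 with no filter, 31 at a mean of at least 1 CPM and 4 at a mean of at least 100, where fewer or more genes were tested by construction. They became 35 with library weights and 27 with median-of-ratios scaling (16 higher, 11 lower); quantile normalization gave 19 (11 higher, 8 lower). Leaving out 1 mouse gave 9 (without WT mouse 3) to 25 (without KO mouse 3); without KO mice 1 and 3 limma called 89 (76 higher, 13 lower), and without WT mouse 1 and KO mouse 3 it called 44 (36 higher, 8 lower). Without chromosome 5 genes and copies 0 were called, since 11 of the called genes besides Hsd17b13 were left out by construction and Ltbp2 and Eif4e3 no longer passed, with 812 of 8587 genes at an unadjusted p under 0.05. Apart from the filters and the genes left out, the cause was not tested.

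For lists, 24 camera calls (19 higher, 5 lower) became 13 with quantile normalization (9 higher, 4 lower), 7 at a mean of at least 100 CPM with 22 lists tested, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 1 with fry; median-of-ratios scaling gave 18 (11 higher, 7 lower). Leaving out 1 mouse gave 17 to 25. Of the list scores, 0 passed the permutation test as reported (8 at an unadjusted p under 0.05), against 6 with quantile normalization, 2 at a mean of at least 1 CPM, 7 with median-of-ratios scaling, 5 without chromosome 5, 4 without KO mice 1 and 3, and 0 to 2 when 1 mouse was left out, 2 without KO mouse 3. The cause of these changes was not tested.

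The type II interferon score, 0.46 as reported, passed at 0.46 with quantile normalization, 0.50 with median-of-ratios scaling, 0.42 without chromosome 5, 0.56 without KO mice 1 and 3 and 0.52 without KO mouse 3, and ran from 0.39 to 0.52 when 1 mouse was left out. The fibrosis score, -0.37 as reported, passed at -0.36 with quantile normalization, -0.32 with median-of-ratios scaling and -0.36 without chromosome 5, with -0.42 to -0.29 when 1 mouse was left out. The Kupffer and activated stellate scores passed in 4 settings each, the quiescent stellate score in 5 and the cholangiocyte score in 3, all of them with quantile normalization and median-of-ratios scaling. The type I interferon score, 0.56 as reported, passed at 0.84 without KO mice 1 and 3 and ran from 0.43 to 0.72 when 1 mouse was left out. The cause of these changes was not tested.

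The mouse numbers shared by the groups do not pair the mice in a steady way: deviations of same-numbered mice correlated at -0.51 to 0.39, and 2 of 12 libraries correlated best with their own number. With the number as a replicate block limma called 11 genes (7 higher, 4 lower, 9 of them among the 14), and camera 24 lists; Hsd17b13 stayed at -7.32. Gbp11 (adjusted p = 0.114), Gpat3, Rplp0, Ltbp2 and Eif4e3 lost their calls there. The sign flips of 6 pairs are too few for a list score to pass unless most lists did, so they say nothing on the scores. Rescaling to a common total moved nothing, because the columns already have equal sums. The edgeR and DESeq2 tests on recovered reads were not run.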

Other observations

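The tests in this part at a mean of at least 1 CPM, on principal components and on mice 1 to 3 against mice 4 to 6 were chosen after the data were seen. At a mean of at least 1 CPM 15648 genes were tested and 31 passed with limma, 16 higher and 15 lower. Genes that fell there include Fbn2, a fibrillin, from 13.4 ± 5.70 to 4.29 ± 1.71 CPM (log2 difference -1.42, adjusted p = 0.0348) and Scube3 from 10.6 ± 5.02 to 3.34 ± 1.25 (adjusted p = 0.0487). The basement membrane collagens fell as well, Col4a5 from 10.9 ± 4.22 to 4.50 ± 1.20 and Col4a6 from 2.37 ± 0.990 to 0.738 ± 0.340 (adjusted p = 0.0495 each). Dpt passed (adjusted p = 0.0473), the only 1 of the 40 fibrosis and matrix list genes tested there that did so over all genes. Krt7, a keratin of bile duct cells, passed too, from 3.61 ± 1.30 to 1.23 ± 0.538 CPM (adjusted p = 0.0495). The interstitial collagenase Mmp13 rose from 6.94 ± 0.755 to 9.79 ± 0.832 CPM (log2 difference 0.44, adjusted p = 0.0453), and the macrophage receptor gene Adgre4 from 7.58 ± 1.10 to 11.6 ± 1.6 (0.55, adjusted p = 0.0495). In a limma fit of all genes Mmp13, Adgre4, Krt7 and Col4a5 did not pass (adjusted p = 0.0517 for Krt7 and Col4a5, 0.0561 for Mmp13 and Adgre4), while Fbn2 (0.0351), Scube3, Col4a6 and Dpt (0.0469 each) did. The chromosome 5 genes Cox18, Fras1, Crlf2, Fam47e and Lgi2 passed as well. These genes were named after their values were seen.

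Of 12 cytotoxic lymphocyte genes, given by their values without a test of the list, 9 had a higher mean in KO. Klrd1 (1.25 ± 0.397 and 0.983 ± 0.178 CPM), Xcl1 (0.647 ± 0.130 and 0.589 ± 0.147) and Prf1 (1.19 ± 0.430 and 1.12 ± 0.216) had a lower one. Granzyme B (Gzmb) was at 0.460 ± 0.157 CPM in WT and 1.24 ± 0.522 in KO (exact permutation p = 0.00216, adjusted p = 0.0837 in a limma fit of all genes, 21 to 109 counts per library). Gzma was at 0.398 ± 0.221 and 1.02 ± 0.399 (0.0964), and the killer cell receptor Klrk1 at 2.69 ± 0.551 and 4.13 ± 0.769 (0.113). Gzmb, Gzma and Klrk1 were picked from the 12 after their values were seen. The permutation p of Gzmb is not adjusted for that choice. At a mean of at least 1 CPM camera called T cell (13 genes, median 0.16, adjusted p = 0.000106; 0.284 with an estimated correlation) and neutrophil markers (6, 0.32, 0.0235; 0.449) higher and gut and mesothelial markers lower (7, -0.32, 0.0223; 0.286). B cell (12 genes, median 0.05, mean -0.16, adjusted p = 0.56), dendritic (11, 0.03, mean -0.08, 0.988) and metalloproteinase genes (8, -0.05, 0.984) were not called. Camera gave the metalloproteinases an upward and the dendritic genes a downward direction, opposite to their medians. Adjusted over the list alone, 2 metalloproteinase genes rose and 3 fell, 2 B cell, 1 dendritic and 1 gut or mesothelial gene fell, and 0 T cell and 0 neutrophil genes passed, 4 T cell genes at an unadjusted p under 0.05. At this minimum the activated stellate (15 genes, -0.41, SE 0.10) and cholangiocyte scores (19 genes, -0.78, SE 0.21, against -0.52 for 9 genes at 10 CPM) passed the exact permutation test (adjusted p = 0.0487 each), with all 6 KO mice below every WT mouse. With no filter 0 of 47 list scores passed that test, 9 at an unadjusted p under 0.05.

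The first principal component of the 9186 genes held 29.4% of the variance and separated the genotypes (exact permutation p = 0.00649), with 5 of 6 KO mice above every WT mouse; without chromosome 5 and copies it held 28.2% (exact permutation p = 0.0238), with 3 of 6 KO mice above every WT mouse. The second held 20.2% and did not follow genotype (exact permutation p = 0.831). Genes at its ends include Ppp1r3g, a glycogen-targeting phosphatase subunit (0.918 to 57.6 CPM across mice), Igfbp1 (32.1 to 431) and Cish (8.67 to 59.4), against the insulin-induced Angptl8 (7.58 to 118) and Bcl6 (9.93 to 90.9).

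Cela1 was at 224 CPM in WT mouse 1 and 94.4 in KO mouse 3, and Cela2a at 149.9 and 73.9; the other 10 mice held 4.99 to 7.25 CPM of Cela1 and 0.216 to 1.00 of Cela2a. These are the 2 of 20 pancreatic list genes in the table. All mice expressed the Y-linked Ddx3y (42.0 to 72.4 CPM) and little Xist (0.192 to 1.36). The erythroid Alas2 was at 50.6 ± 7.80 CPM in WT and 53.2 ± 3.69 in KO.

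The 2 most abundant features without a symbol, ENSMUSG00000118866 and ENSMUSG00000118841, held 4.26% and 4.07% of the counts and were higher in mice 1 to 3 than in mice 4 to 6 within both genotypes. A total of 36 tested genes separated mice 1 to 3 from mice 4 to 6 within both genotypes, where chance gives 45.9. Rpph1 and Scarna2 also did so, in the same direction as these 2 features. Rpph1 averaged 4043 CPM in WT mice 1 to 3 and 2615 in WT mice 4 to 6, and 3477 and 2035 in KO. The count over all genes therefore does not exclude a difference in a few abundant RNAs. With a term for this division, added after seeing the data, limma called the same number of genes, 14, and camera 23 lists. The size of the list score differences was nevertheless unequal. The type I interferon score differed by 0.24 between mice 1 to 3 and by 0.88 between mice 4 to 6. For type II interferon these values were 0.33 and 0.59, and for MHC class II 0.12 and 0.50. The fibrosis score went the other way, with -0.49 and -0.24. KO mice 1 and 3, set apart above, both belong to mice 1 to 3.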
